A study of Homo sapiens with 19 samples.

How the data were processed

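Chromatin immunoprecipitation with hybridisation to 2-colour promoter tiling arrays (ChIP-chip) was analysed for 19 arrays. Per the labels, each array set immunoprecipitated DNA in the Cy5 channel against input DNA in the Cy3 channel, with no array in the reverse orientation. Histone H3 acetylated at lysine 56 (K56ac), acetylated at lysine 9 (K9ac), trimethylated at lysine 4 (K4me3) and trimethylated at lysine 27 (K27me3) were each measured once in 4 cell lines, HSF1, HSF6, ARPE and BJ. One further array held K56ac in HSF6 after retinoic acid, and histone H3 itself, whatever its modification, was measured once in HSF6 and once in ARPE.

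The deposited table of each sample holds scanner intensity values per spot, foreground and local background for both channels, from Agilent Feature Extraction (per the submitters' processing notes, version not given in the sources used here). It also holds intensity values that the authors background-corrected and normalized between channels, and a normalized ratio on the log2 scale. The deposited log2 ratio equalled the log2 of normalized immunoprecipitate over normalized input within 8.5e-07 on every array. The mean deposited log2 ratio was near 0 in each of 10 equal groups of probes ordered by intensity, at most 0.02 from it, whereas plain background-subtracted signals of K4me3 in ARPE ran from -1.34 at the dim end to 1.66 at the bright end. The authors' normalization therefore depended on intensity; its method was not given in the sources used here. Other deposited columns are 0 or 1 flags of the authors' program for excluded probes and for probes inside regions it called bound. The series matrix held the same deposited log2 values, with a largest difference of 0.0 over matched probes, and column medians from -0.30 to 0.03.

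Each array covers 474411 data probes on 2 slides (473844 in the K4me3 file of HSF6), with 12568 control spots (12560 in that file), which were left out. The design had named processed signals of the scanner software; the tables do not carry these columns, so the deposited normalized log2 ratio took their place. Probes that the authors excluded were left out (413 to 4572 per array, 11927 on the retinoic acid array), each array was centred on the median of its probes, and no loess or quantile step was added. A gene's value is the mean over the probes that the array annotation assigns to that gene alone, with at least 3 probes. The annotation gave 17647 genes at least 1 probe of their own, with a median of 24 probes per gene; 12343 probes lie in promoters shared by a pair of genes and 6126 have no gene. Gene names were brought up to date through a RefSeq table, by accession for 17994 name and accession pairs, by current symbol for 744 and by a unique synonym for 603; 554 kept the name in the files. The genome build is not given in the sources used here, so positions are printed as the array annotation gives them. The retinoic acid array carried another version of the annotation, and the version shared by the other 18 arrays was used for it. Chromosomes X and Y were left out of every test, which left 16613 genes.

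Signal over background in the immunoprecipitate channel, the ratio of median foreground to median local background, was 4.38 to 14.15 on the arrays of the 4 marks, 8.42 and 9.09 on the H3 arrays and 3.44 on the retinoic acid array. For these arrays the number of arrays limits the precision.

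HSF1 and HSF6 (human embryonic stem cell lines, hESC) were compared with ARPE and BJ (somatic lines) for each mark separately with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, adjusted p under 0.05). Each line is 1 replicate of its class; the p-values measure the spread between lines of a class, each with a single array per mark. Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over 14 lists and 4 marks (56 tests). The correlation estimated from the data and fry were alternatives. With an estimated correlation camera also uses the residual degrees of freedom, which are few for 4 arrays in 2 groups. No list of any mark passed with it (lowest adjusted p = 0.62). This held even at an estimate below 0.01, as for K27me3 at blood and liver genes (-0.005). This alternative therefore cannot tell whether correlation between genes undid a call. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Whether the hESC effect differed between marks was tested with limma on within-line differences of values scaled per array to a median absolute deviation (MAD, times 1.4826) of 1. Correlations between marks were computed across genes within each line, and classes were compared by an exact two-sided permutation test of the 4 lines. A gene was called enriched on an array when its value exceeded the median over genes by more than 2 times the distance from the 15.87th percentile to the median, and in a class when called in both lines. Retinoic acid and H3 comparisons have 1 array per condition and no test: a list's median difference was placed among 10000 random lists of the same size matched in 20 bins on mean value. Probe values were averaged in 500 bp bins of distance to the annotated transcription start.

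The comparisons, the gene lists, the alternatives and the rule for named genes were set before the data were examined. The rule names, for K56ac, the 12 genes with the largest difference in each direction that passed the threshold with both hESC lines on one side of both somatic lines, and 6 in each direction for the other marks. It adds POU5F1, NANOG and SOX2 for every mark and up to 4 members per list, for lists that passed camera and for the pluripotency, developmental transcription factor, mesenchymal and histone lists in any case. For differences between marks it names 6 in each direction, and for retinoic acid and H3 10 in each direction plus up to 4 members of each list outside the random range. Placeholder symbols are not named, and a few genes that the rule picks are not reported here. The alternatives covered normexp background correction (offset 50) of the scanner signals, the series matrix, MAD scaling, centring on the mode, intensity-dependent loess, dim and excluded probes, other summaries over a gene's probes, other probe minimums (1 and 10), shared probes, chromosome X, a fit over 16 arrays in 8 groups with and without the cell line as a block, eBayes with trend and robust, thresholds of 0.1 and 0.01, scan batch as a block and leaving out each line in turn. In the normexp alternative no intensity-dependent normalization between channels was made. The loess alternative was fitted to these normexp values within each slide, not to the main values. Centring the slides separately, single slides of the retinoic acid array and the authors' bound regions were added after seeing the data.

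Scan batches were read from the scan folders that the tables record. For K56ac, one batch held ARPE and HSF1 and another BJ and HSF6, and the same held for slide 1 of K9ac, so that batch could be a block and values could be given within each batch. For K4me3 and K27me3 each line was scanned in a batch of its own, so that batch and line cannot be told apart. The retinoic acid array was scanned in another batch than untreated HSF6, and the H3 arrays in other batches than the K56ac arrays, so those comparisons are also confounded with batch. The tables record the same slide for slide 2 of K9ac and of H3 in HSF6, although the values differ (r = -0.499 between these arrays across genes), so 1 of these records is in doubt. The input of each slide was compared with the same slide of the other arrays by Pearson correlation of log2 background-subtracted signals over all data probes, excluded ones too.

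The fit was tested on simulated data with the arrays' own spread, 100 genes shifted by log2 1 and 100 by log2 2. For K56ac 24% of the smaller and 71% of the larger shifts were recovered, for K9ac 35% and 75%, for K4me3 43% and 83%, and for K27me3 44% and 74%, with 2 to 4 unshifted genes called. In the same data camera called the 1 list that had been shifted for every mark, and up to 2 of the other lists at an unadjusted p under 0.05. The simulation was built on the arrays' spread and not on their correlation between genes. In the real arrays this correlation was estimated at -0.017 to 0.744 over the 56 list tests. The simulation therefore cannot show how often camera at its preset correlation makes false calls on the real arrays. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.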

Results

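Histone H3 modifications were mapped at human promoters by ChIP-chip in 4 established cell lines. HSF1 and HSF6 are embryonic stem cell lines. ARPE and BJ are somatic lines. K56ac, an acetylation inside the globular domain of H3, was measured together with K9ac and K4me3, marks of active promoters, and K27me3, the mark of Polycomb repression. Each class had 2 lines per mark (16 arrays). HSF6 was also measured for K56ac after retinoic acid (1 array), and H3 itself was measured in HSF6 and ARPE (1 array each). Values are log2 ratios of immunoprecipitate over input, averaged over each gene's own probes and centred per array, for 16613 autosomal genes, and medians given with MAD scaling (each array scaled to a median absolute deviation of 1) are in MAD units. Signal over background ran from 4.38 to 14.15 on the arrays of the 4 marks and was 3.44 on the retinoic acid array, and the number of arrays limits the precision. Across genes, K56ac correlated at r = 0.873 between the hESC lines and at 0.821 between the somatic lines, against 0.401 to 0.539 across classes.

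The first comparison asked at which promoters K56ac differs between hESC and somatic lines, since the series links this mark to the transcriptional network of hESC. K56ac was higher in hESC at the pluripotency genes NANOG, DPPA4, LIN28B, SOX2, GDF3 and POU5F1 and at the microRNA clusters of chromosome 19 that are active in pluripotent cells. It was lower at mesenchymal and extracellular matrix genes such as NNMT, FAP and COL3A1, and at the hair keratin KRT34. NANOG, a core pluripotency transcription factor (chromosome 12, probes from 7828567 to 7835704), stood at 1.76 in hESC and -0.71 in somatic lines, a difference of 2.46 ± 0.29 (SE, n = 2 lines per class, adjusted p = 0.0186). KRT34 (chromosome 17, 18 probes) showed the reverse, -0.22 in hESC against 3.05 in somatic lines (-3.27 ± 0.12, adjusted p = 0.0182).

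Among 46 measured pluripotency genes, 33 were higher and 1 was lower in hESC over all genes tested, and 36 and 1 adjusted over the list alone. The list median difference was 1.06 (camera adjusted p = 1.02e-15, and adjusted p = 0.62 with an estimated correlation). With normexp 18 were higher and 1 lower (median 0.50), with MAD scaling 39 and none, and with loess no gene of the list was called (0.56), while the list test still passed. DPPA4, a chromatin factor of pluripotent cells, differed by 2.63 ± 0.31. LIN28B, which blocks let-7 maturation, differed by 2.27 ± 0.40 and GDF3, a TGF-beta family ligand, by 2.02 ± 0.14. POU5F1 (Oct4) differed by 0.97 ± 0.14 and SOX2 by 1.93 ± 0.33, though in the 3 adjacent probes with the highest mean SOX2 turned to -0.86 (adjusted p = 0.449). The genes with the largest gains also held GALNT8, a glycosyltransferase (chromosome 12, 4694591 to 4702631), at 2.84 ± 0.20. FBXO40, an F-box protein (chromosome 3, 122794462 to 122797307), had means of 1.70 in hESC and -1.09 in somatic lines. On chromosome 19 the microRNAs hsa-mir-512-1 (2.83 ± 0.23), MIR498 (2.57 ± 0.13) and hsa-mir-520e (2.15 ± 0.24) belong to one cluster. MIR371A (hESC mean 1.43, somatic mean -1.07) and MIR373 (2.14 ± 0.18) belong to its neighbour. LRRTM4, a synaptic adhesion protein (2.31 ± 0.23), and F11, coagulation factor XI (2.08 ± 0.20), completed the 12 largest.

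Of 84 mesenchymal and extracellular matrix genes, 51 were lower and none higher in hESC, and 59 were lower adjusted over the list alone. The list median was -0.89 (adjusted p = 1.22e-10, and adjusted p = 0.62 with an estimated correlation). With MAD scaling 1 was higher and 14 were lower (-0.70 MAD units), with mode centring 32 were lower, with normexp 49 and with loess none, while the list test still passed. NNMT, nicotinamide N-methyltransferase, differed by -2.95 ± 0.17, COL3A1, a fibrillar collagen, by -2.12 ± 0.43, and ANXA1 by -2.02 ± 0.23. FAP, a fibroblast surface protease, stood at -0.27 in hESC and 2.23 in somatic lines. Outside the list, LMO7 (-3.04 ± 0.32), the tyrosine kinase ABL2 (-2.94 ± 0.18), RBKS (-2.75 ± 0.22) and hsa-mir-216 (-2.74 ± 0.12) were among the most reduced. ASB5 (-2.60 ± 0.11) and the hair keratin KRT33B (-2.49 ± 0.28) followed, with ACKR4, SERPINB7 and ZC3H7A between -2.39 and -2.30.

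CDK inhibitors and p53 targets had a K56ac median of -0.48 (adjusted p = 1.28e-04, and adjusted p = 0.62 with an estimated correlation), but with MAD scaling the median was 0.00 MAD units and the call was lost (adjusted p = 0.928). Of its 35 genes 1 was higher and 18 were lower, and 2 and 22 adjusted over the list alone, while with MAD scaling 4 were higher and 2 lower. GADD45A (-1.51 ± 0.13), CDKN2C (-1.48 ± 0.24) and PLK2 (-1.35 ± 0.22) were among the most reduced of this group. Ribosomal protein and housekeeping genes had a median of -0.43 (adjusted p = 5.3e-05, and adjusted p = 0.62 with an estimated correlation), which turned to 0.29 MAD units with MAD scaling (adjusted p = 0.274). Of these 71 genes 20 were lower and none higher, and 19 were lower adjusted over the list alone, while with MAD scaling 3 were higher and 2 lower.

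The lists of lineage genes had higher K56ac ratios in hESC. At named members such as GAD2, CER1, MIXL1 and EOMES somatic means lay below 0 and hESC means above it. At RUNX1, PAX8 and KRT7 the somatic means lay above the hESC means. Of 163 developmental transcription factors, 32 were higher and 3 lower, and 24 and 3 adjusted over the list alone (median 0.28, adjusted p = 3.67e-09). GLI3, a Hedgehog pathway factor, differed by 1.43 ± 0.17, while RUNX1 (-1.63 ± 0.16) and PAX8 (-1.12 ± 0.22) went the other way. For neural genes 13 of 49 were higher and none lower, with 12 higher adjusted over the list alone (median 0.44, adjusted p = 2.21e-08). For mesoderm and endoderm genes 14 of 37 were higher and none lower, with 16 higher adjusted over the list alone (median 0.40, adjusted p = 8.65e-08). For trophoblast and germline genes 15 were higher and 2 lower of 37, with 18 and 2 adjusted over the list alone (median 0.46, adjusted p = 2.33e-06). With normexp the calls became 6 higher and 9 lower for developmental transcription factors (median 0.03), 4 and none for neural (0.17), 2 and 2 for mesoderm and endoderm (0.27) and 4 and 3 for trophoblast and germline genes (0.18), while the list tests still passed. Each of these lists had adjusted p = 0.62 with an estimated correlation. GAD2, the enzyme that makes GABA (1.70 ± 0.22), CER1, a secreted endoderm antagonist (1.75 ± 0.29), MIXL1 (1.20 ± 0.12), EOMES (1.17 ± 0.21) and DAZL of germ cells (1.31 ± 0.19) rose, and KRT7 fell by 1.63 ± 0.10. TBXT rose by 1.03 ± 0.16 over all its probes and stood at -0.29 in its highest 3-probe window. Blood and liver genes, which belong to neither class, also had higher ratios, with 26 of 52 higher and none lower, and 30 and 1 adjusted over the list alone (median 0.47, adjusted p = 4.12e-10, and adjusted p = 0.62 with an estimated correlation). With MAD scaling 5 of them were higher and none lower, and with normexp 11 and 2. At CD3E, a T cell receptor subunit, the means were -0.08 in hESC and -1.05 in somatic lines (0.97 ± 0.11).

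Replication-dependent histone genes had a K56ac list median of 0.41 (adjusted p = 2.66e-04, and adjusted p = 0.651 with an estimated correlation), but with normexp background correction it was -0.11 and the call was lost (adjusted p = 0.216). H2AC16 (0.98 ± 0.24) and H2BC15 (0.78 ± 0.20, and -0.13 with normexp) were the 2 of 41 genes called higher, and none was called adjusted over the list alone. With MAD scaling 32 were called higher and none lower (median 4.08 MAD units, adjusted p = 3.16e-17), and with normexp 3 and 4. H4C6 and H4C13 had larger but more variable values, 1.77 ± 0.74 and 1.71 ± 0.74, with ARPE at -1.17 and -1.07 and BJ at 0.75 and 0.99. The remaining lists did not pass for K56ac. Cell cycle genes had 2 higher and 10 lower of 58, and 1 and 6 adjusted over the list alone (median -0.16, adjusted p = 0.469), but with MAD scaling 12 were higher and 3 lower (0.23 MAD units). Pigment epithelium genes had 8 and 9 of 35 by either count (adjusted p = 0.331). Retinoic acid genes had 4 and 12 of 59, and 4 and 11 adjusted over the list alone (adjusted p = 0.343). Stem cell regulators had 3 and 6 of 36, and 1 and 5 adjusted over the list alone (adjusted p = 0.831). The pigment epithelium and retinoic acid lists had medians above 0 (0.12 and 0.07), a camera direction of higher and means below 0 (-0.08 and -0.12). Stem cell regulators had a median of -0.16 with a camera direction of higher, and with MAD scaling their median was 1.19 MAD units, 13 were higher and 1 lower and they passed (adjusted p = 1.52e-06), while with normexp 1 was higher and 11 lower. Retinoic acid genes also passed with MAD scaling (0.0314), with 7 higher and 4 lower, and with normexp 1 was higher and 16 lower.

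In all, 1899 genes were higher and 3268 lower in hESC for K56ac (limma), and with scan batch as a block 1289 and 2411. Both hESC lines lay on one side of both somatic lines at 76.2% of genes, where chance gives 33.3%. This chance value, used for every mark, assumes arrays of equal spread. The ratio of hESC to somatic SD was 0.46 for K56ac, 0.69 for K9ac and 1.24 for K4me3. Unequal spread can raise the share by itself, and genes are not independent, so the excess over 33.3% is descriptive only. Within the scan batch of HSF1 and ARPE and that of HSF6 and BJ, the medians were 1.03 and 1.11 for pluripotency and -0.75 and -1.10 for mesenchymal genes. They were 0.52 and 0.14 for developmental transcription factors and 0.29 and 0.52 for histone genes, and every other list called for K56ac also kept its sign in both batches. The median over all genes was -0.12, and 0.01 MAD units with MAD scaling and log2 0.04 with mode centring. The share of calls that were higher, 36.8%, moved to 56.4% with MAD scaling, 58.7% with mode centring and 13.5% with normexp. No gene passed in limma without HSF1 (1358 higher and 2147 lower at an unadjusted p under 0.05) or without HSF6 (1364 and 3076). Without ARPE 2833 and 5266 passed, without BJ 3900 and 5549, and after loess 0 and 1 (698 and 1770 at an unadjusted p under 0.05).

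**Figure D1:**
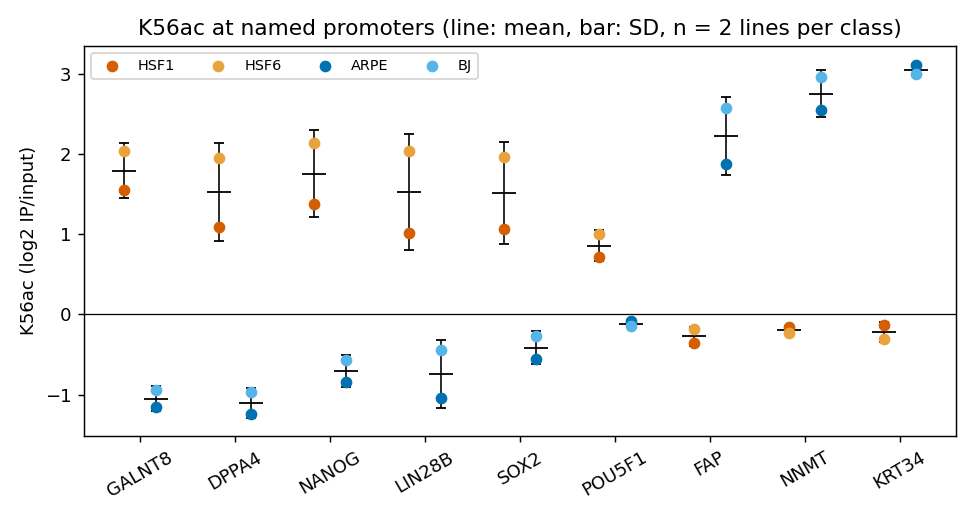
K56ac (log2 immunoprecipitate over input, y axis) at 9 named genes (x axis) in HSF1, HSF6, ARPE and BJ; points are single lines, horizontal lines are class means and bars the SD (n = 2 lines per class). NANOG stood at 1.76 in hESC and -0.71 in somatic lines and KRT34 at -0.22 and 3.05, and the SOX2 difference turned to -0.86 in its highest 3-probe window.

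The K9ac comparison asked whether the class difference is shared by an acetylation of active promoters. Pluripotency genes again had the highest list median, 0.36, and mesenchymal genes the lowest, -0.28. No single gene passed in limma, with 467 higher and 736 lower at an unadjusted p under 0.05, and 171 and 201 passed with the trend and robust options of eBayes. LIN28B differed by 1.53 ± 0.20, DPPA4 by 1.47 ± 0.18, the Nodal co-receptor CRIPTO by 1.42 ± 0.18 and NANOG by 1.25 ± 0.20 (n = 2 lines per class, adjusted p = 0.663 for each), with both hESC lines above both somatic lines. SPARC (-0.89 ± 0.16), NNMT (-0.85 ± 0.18) and FAP (-0.73 ± 0.22) had the opposite sign. Adjusted over the list alone, 18 of 46 pluripotency genes were higher, and no gene of any other list was called. Classes lay apart at 40.8% of genes, where chance gives 33.3%.

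The K9ac list tests passed as higher for pluripotency (adjusted p = 9.83e-25), neural (median 0.14, 1.34e-09), blood and liver (0.13, 9.2e-06), histone (0.18, 3.55e-05), mesoderm and endoderm (0.09, 9.37e-05) and trophoblast and germline genes (0.08, 4.52e-04). They passed as lower for mesenchymal (1.28e-11), ribosomal and housekeeping (-0.18, 3.93e-05) and CDK inhibitor and p53 genes (-0.20, 1.75e-03). None of these passed with an estimated correlation (adjusted p = 0.62, and 0.662 for ribosomal genes), where no list of any mark passed. Developmental transcription factors passed as higher (adjusted p = 0.0263, and adjusted p = 0.762 with an estimated correlation) although their median and mean were -0.00. With MAD scaling the direction turned for the blood and liver, developmental, trophoblast and ribosomal lists, the last with a median of 0.28 MAD units, and the calls of the CDK inhibitor (adjusted p = 0.0617) and of the mesoderm and endoderm list (0.0505) were lost. Cell cycle, pigment epithelium, stem cell and retinoic acid genes did not pass (adjusted p = 0.488, 0.604, 0.43 and 0.483). The first 3 of these had medians below 0 (-0.01, -0.03 and -0.06) with a test direction of higher. With MAD scaling cell cycle genes (median 0.48 MAD units, adjusted p = 5.43e-07) and stem cell regulators (0.69 MAD units, 1.38e-06) passed as higher and retinoic acid genes as lower (-0.16 MAD units, 1.68e-03).

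The K9ac scan batches hold for slide 1 only, since slide 2 of all K9ac arrays was scanned in a single batch, while the medians cover genes of both slides. Within scan batches the K9ac medians kept their sign at pluripotency genes (0.31 for HSF1 and ARPE, 0.44 for HSF6 and BJ) and at mesenchymal genes (-0.28 and -0.19). They had opposite signs at histone genes (-0.20 and 0.56), ribosomal genes (-0.47 and 0.05) and developmental transcription factors (0.12 and -0.09), and were near 0 in the second batch for blood and liver and for mesoderm and endoderm genes (-0.00 each). Leaving out ARPE ended the calls of the blood and liver (adjusted p = 0.435), mesoderm and endoderm (0.179), trophoblast (0.108), ribosomal (0.165) and developmental lists (0.249, direction lower). Leaving out HSF1 ended those of the mesoderm and endoderm (0.0602) and developmental lists (0.0742, direction lower), and leaving out HSF6 that of histone genes (0.802). Cell cycle, retinoic acid and stem cell lists passed without HSF1 (3.62e-04, 2.36e-03 and 0.0347) and without ARPE (0.0136, 0.033 and 0.0339).

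The K4me3 comparison asked whether promoters that differ in acetylation also differ in a methylation of active starts. K4me3 was higher in hESC at the miR-302 cluster and at LARP7, whose intron hosts it, at CRIPTO, NANOG and VRTN. It was lower at interferon-responsive GBP3 and SAMD9L, at the antigen-presenting MR1 and at NNMT. hsa-mir-302b (chromosome 4, 33 probes) stood at 1.77 in hESC and -1.03 in somatic lines (2.80 ± 0.18, n = 2 lines per class, adjusted p = 1.1e-03). GBP3 (chromosome 1, 12 probes) stood at -0.80 and 1.94 (-2.74 ± 0.15, adjusted p = 8.08e-04). LARP7 differed by 3.06 ± 0.22, CRIPTO by 2.38 ± 0.20, hsa-mir-141 by 2.25 ± 0.20, NANOG by 2.18 ± 0.23 and VRTN by 2.06 ± 0.20. hsa-mir-99a (-2.52 ± 0.19), MR1 (-2.46 ± 0.24), SAMD9L (-2.46 ± 0.17) and NNMT (-2.44 ± 0.21) were among the most reduced. So was UGT2B17 (-2.78 ± 0.22), a gene with 3 probes whose H3 value in HSF6 was also low, -2.92.

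By list, 21 of 46 pluripotency genes were higher in K4me3 and 1 was lower, and 28 and 2 adjusted over the list alone (median 0.61, adjusted p = 4.24e-14), with POU5F1 at 1.04 ± 0.16, SOX2 at 1.28 ± 0.23 and DPPA4 at 1.58 ± 0.17. With normexp 4 were higher (median 0.39), with MAD scaling 7 (0.57 MAD units) and with loess 8 (0.41), and the median was 0.19 with mode centring. Mesenchymal genes were lower at 18 of 84 and higher at none, and 29 and 1 adjusted over the list alone (median -0.29, adjusted p = 2.68e-08), led after NNMT by FAP (-2.08 ± 0.16) and ANXA1 (-1.63 ± 0.25), and with normexp 1 was lower and with mode centring 53. Developmental transcription factors had 11 higher and 1 lower of 163, and 13 and 1 adjusted over the list alone (median 0.35, adjusted p = 2.01e-12), but with loess the median was 0.03 and 2 were called, and with normexp 0.04 and 1. Mesoderm and endoderm genes had 4 higher and none lower of 37, and 16 and 1 adjusted over the list alone (median 0.48, adjusted p = 4.67e-06), with medians of 0.09 after loess and 0.17 with normexp. Of them none was called with MAD scaling or normexp, and mode centring called 2 higher and 4 lower (median 0.06). All of these lists had adjusted p = 0.62 with an estimated correlation. GLI3 (1.28 ± 0.17), SOX11 (1.07 ± 0.18), CER1 (1.15 ± 0.19) and GSC (0.99 ± 0.19) rose.

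Cell cycle genes had 5 higher and none lower of 58, with 7 higher adjusted over the list alone (median 0.24, adjusted p = 3.23e-06), and with MAD scaling the median was -0.02 MAD units while the list still passed (0.0184). Stem cell regulators had 4 and none of 36, with 7 higher adjusted over the list alone (median 0.21, adjusted p = 3.93e-05), but with MAD scaling the median was -0.05 MAD units and the call was lost (0.0818). Histone genes had 3 and 1 of 41, with 8 and 1 adjusted over the list alone (median 0.42, adjusted p = 1.56e-05), but with loess the median was -0.01 and the call was lost (0.147). Neural genes had 5 and none of 49, with 7 higher adjusted over the list alone (median 0.11, adjusted p = 0.0112, and -0.01 with loess), and their call was lost without ARPE (0.112) and with the median over probes (0.0716). With mode centring 1 was higher and 7 were lower of the neural genes, none and 3 of the cell cycle genes, 5 and 4 of the histone genes and none of the stem cell regulators. With loess or normexp no neural, cell cycle or stem cell gene was called. ORC6 of the origin recognition complex (0.82 ± 0.18), the helicase subunit MCM4 (0.81 ± 0.16), FGFR2 (0.87 ± 0.16) and GAP43 (1.06 ± 0.16) rose. Blood and liver genes had 1 higher and 7 lower of 52, with 2 and 12 adjusted over the list alone (median -0.27, adjusted p = 5.3e-05). Trophoblast and germline genes had none higher and 7 lower of 37, with 10 lower adjusted over the list alone (median -0.28, adjusted p = 1.01e-03), and both calls were lost with MAD scaling or loess. The trophoblast call was also lost with normexp (camera adjusted p = 0.152). No gene of these lists was called with MAD scaling or normexp, while mode centring called 34 blood and liver and 24 trophoblast genes lower. Ribosomal and housekeeping genes passed as higher with none of 71 genes called on either side by either count (median 0.13, adjusted p = 6.59e-03). With MAD scaling (-0.18 MAD units, 0.0953), normexp (median 0.01, 0.054) or loess (0.963) they did not. Without HSF6 their median was 0.01. With an estimated correlation, where no list of any mark passed, these lists did not either (adjusted p = 0.62, 0.664 for neural and 0.662 for ribosomal genes). CDK inhibitor (median -0.04, adjusted p = 0.483), pigment epithelium (-0.10, 0.228) and retinoic acid genes (0.20, 0.0759) did not pass. CDK inhibitor genes passed as lower with loess (0.018), MAD scaling (0.0182) and normexp (0.0418), and retinoic acid genes as higher without BJ (1.26e-03), in the highest 3-probe window, within 1000 bp of the start and with the trend and robust options.

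Over all genes K4me3 was higher at 423 and lower at 855, with classes apart at 57.7% of genes where chance gives 33.3%. The median over all genes moved from 0.01 to -0.41 with mode centring, -0.11 with normexp and -0.13 with loess, and was -0.11 MAD units with MAD scaling. With mode centring the list medians of developmental (-0.07), cell cycle (-0.18), neural (-0.30), stem cell (-0.21) and ribosomal genes (-0.29) lay below 0, while their directions against other genes stayed. The counts were 9 and 22 with normexp, 135 and 4685 with mode centring and 1299 and 1612 with the trend and robust options, and the share of calls that were higher moved from 33.1% to 2.8% with mode centring and 22.6% with loess. No gene passed in limma without HSF1 (1862 higher and 1289 lower at an unadjusted p under 0.05) or without HSF6 (964 and 2262). For K4me3 and K27me3 each line was scanned in a batch of its own, so batch and line cannot be told apart.

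The K27me3 comparison asked which promoters Polycomb marks differently. In hESC it was higher at developmental transcription factors, with TBX5 of heart and limb, SIM1, HLX, FOXF2 and HOXA9 leading. It was lower at blood and liver genes such as LYZ, at CXCL10 and KRT26, and at LIN28B. TBX5 (chromosome 12, 69 probes) stood at 2.96 in hESC and -0.04 in somatic lines (n = 2 lines per class, adjusted p = 8.49e-03). CXCL10, a chemokine, stood at -0.33 and 1.90 (-2.23 ± 0.12, adjusted p = 8.49e-03). SIM1 differed by 2.66 ± 0.16, CCDC92 by 2.57 ± 0.11, FGF5 by 2.41 ± 0.09 and KIRREL3 by 2.38 ± 0.20, and GIMAP5 stood at 2.74 in hESC and -0.12 in somatic lines. NRG4 (-2.35 ± 0.26), GAPT (-2.11 ± 0.30), TEX15 (-2.01 ± 0.20), LEMD1 (-2.01 ± 0.12) and KRT26 (-1.94 ± 0.13) were among the most reduced.

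Of 163 developmental transcription factors, 86 were higher and none lower in K27me3, and 135 were higher adjusted over the list alone (median 0.99, adjusted p = 1.14e-31). With MAD scaling 7 of them were higher, with loess 51, with mode centring 81 and with normexp 95, while the list test still passed. HLX (2.36 ± 0.12), FOXF2 (2.26 ± 0.14) and HOXA9 (2.22 ± 0.34) followed TBX5. Retinoic acid genes had 19 higher and 2 lower of 59, and 29 and 2 adjusted over the list alone (median 0.65, adjusted p = 5.05e-10), with MEIS1 (2.05 ± 0.10), NR2F1 (1.87 ± 0.09) and HOXA3 (1.64 ± 0.16), and with MAD scaling 2 and none were called. Mesoderm and endoderm genes had 11 and 4 of 37, and 19 and 4 adjusted over the list alone (median 0.62, adjusted p = 1.76e-04), with HAND2 (2.10 ± 0.28) and ISL1 (1.77 ± 0.18), and with MAD scaling 1 and 1 were called. Mesenchymal genes had 14 of 84 higher and none lower by either count (median 0.14, adjusted p = 1.52e-03), among them the regulator TWIST1 (1.81 ± 0.21) and COL12A1 (1.58 ± 0.13), with 8 higher with MAD scaling and 6 with loess. CDK inhibitor and p53 genes had 3 and none of 35, and 3 and 1 adjusted over the list alone (median 0.13, adjusted p = 0.0359), with CDKN2C (2.30 ± 0.16) and CDKN2B (1.56 ± 0.14), and their call was lost without HSF1 (0.0794) or ARPE (0.0522). Histone genes had 3 and none of 41, and none adjusted over the list alone (median 0.22, adjusted p = 1.01e-03), and their call was lost without BJ (0.111), in the fit over 16 arrays (0.144) and in the highest 3-probe window (0.345). Cell cycle genes passed with none of 58 called by either count (median 0.16, adjusted p = 6.71e-03), and lost the call with loess (0.0894), with normexp (0.232) and in the highest 3-probe window (0.128). All of these lists had adjusted p = 0.62 with an estimated correlation.

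Blood and liver genes were lower in K27me3, with none higher and 15 lower of 52, and 20 lower adjusted over the list alone (median -0.26, adjusted p = 1.34e-08). So were trophoblast and germline genes, with 4 and 9 of 37, and 6 and 14 adjusted over the list alone (median -0.41, adjusted p = 6.25e-04). Both had adjusted p = 0.62 with an estimated correlation, and with MAD scaling none and 3 were called for the first and 2 and 4 for the second. Pluripotency genes had 3 higher and 10 lower of 46, and 5 and 14 adjusted over the list alone (median -0.27, adjusted p = 0.0263, and adjusted p = 0.645 with an estimated correlation), and their call was lost without HSF1 (0.0565) or BJ (0.509) and with the median over probes. LYZ, lysozyme (-1.66 ± 0.15), the liver enzyme G6PC1 (-1.39 ± 0.12), ZP2 of the egg coat (-1.31 ± 0.12) and SALL4 (-0.96 ± 0.14) fell. LIN28B stood at 0.44 in hESC and 1.84 in somatic lines over all its probes, and at a difference of 0.25 in its highest 3-probe window. NANOG (-0.63 ± 0.28), SOX2 (-0.60 ± 0.26, and 1.30 in its highest window) and POU5F1 (0.26 ± 0.10) did not pass. Neural genes (11 higher and 2 lower of 49, 15 and 6 adjusted over the list alone, median 0.11, adjusted p = 0.365), pigment epithelium (-0.02, 0.343), stem cell (0.09, 0.399) and ribosomal genes (0.12, 0.0529) did not pass either, and ribosomal genes passed without HSF1 (0.0445).

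Over all genes K27me3 was higher at 656 and lower at 1026, with classes apart at 60.6% of genes where chance gives 33.3%. The counts were 224 and 360 with MAD scaling, 296 and 434 with loess and 422 and 494 with normexp. No gene passed in limma without HSF1 (1007 higher and 1316 lower at an unadjusted p under 0.05) or without HSF6 (1485 and 1426). Without ARPE 1346 and 2070 passed, and without BJ 1395 and 1950.

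**Figure D2:**
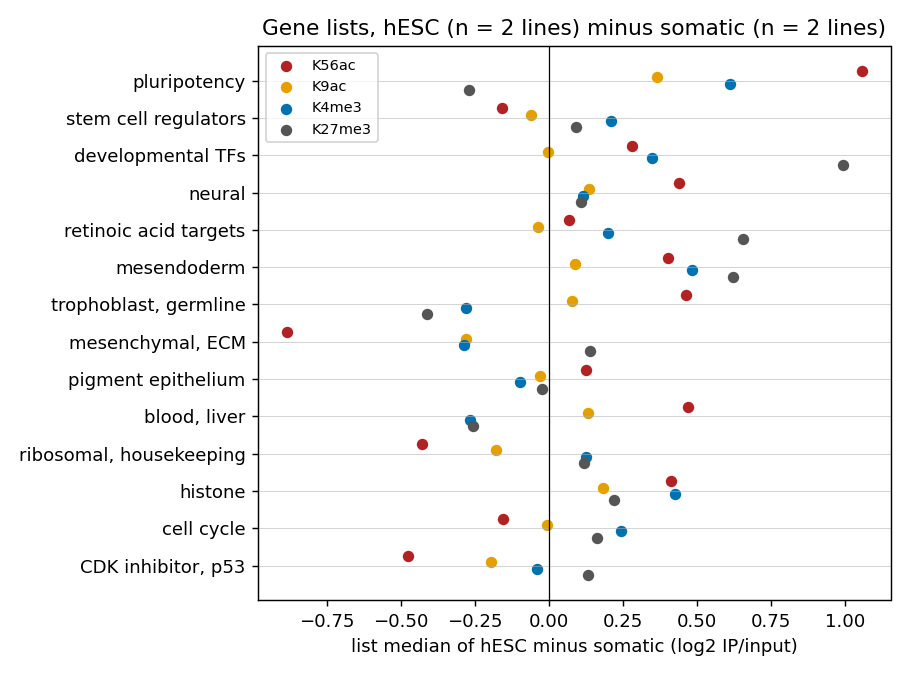
List median of the hESC minus somatic difference (log2, x axis) for 14 gene lists (y axis) and 4 marks (colours, 2 hESC lines and 2 somatic lines). Pluripotency genes lay at 1.06 for K56ac and developmental transcription factors at 0.99 for K27me3, while with MAD scaling, in MAD units, the ribosomal median turned to 0.29 for K56ac, 0.28 for K9ac and -0.18 for K4me3, and the histone median for K56ac was -0.11 with normexp.

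Whether the hESC minus somatic effect of K56ac lies above or below that of the other marks was tested on scaled values within lines. The effect keeps its sign, so a lower effect can be a larger loss. At MIR15A, called lower against K4me3, the log2 effect was -1.46 for K56ac and -0.08 for K4me3. Against K4me3, 1612 genes had a higher and 995 a lower hESC effect for K56ac, and with normexp the balance turned to 748 and 1662. hsa-mir-512-1 (9.49 ± 0.30 MAD units, n = 2 lines per class), GALNT8 (8.45 ± 0.33), MIR498 (8.43 ± 0.46) and FBXO40 (7.71 ± 0.43) led. On the other side stood neighbouring olfactory receptor genes, OR4K2 (-5.86 ± 1.40), OR4K5 (-4.67 ± 1.18) and OR4K1 (-4.27 ± 0.84, and 0.26 with normexp), at which ARPE and BJ also lay far apart. Without HSF1 the counts became 697 and 198. Against K9ac, GALNT8 (7.96 ± 0.36, adjusted p = 0.0355) and hsa-mir-512-1 (7.41 ± 0.34, adjusted p = 0.0355) passed as higher and none as lower (limma, 1548 and 1342 at an unadjusted p under 0.05). This count became 573 and 999 without HSF6 and 0 on both sides without ARPE (556 and 857 at an unadjusted p under 0.05) or without BJ (680 and 304).

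How far K56ac goes with the other marks within a line was described by correlations across genes, which are not independent replicates. K56ac rose with K9ac in every line, at r = 0.365 in HSF1, 0.663 in HSF6, 0.848 in ARPE and 0.662 in BJ. With K4me3 it gave 0.343 and 0.541 in hESC and 0.625 and 0.679 in somatic lines. With K27me3 the sign differed between classes, 0.245 and 0.109 in HSF1 and HSF6 against -0.407 in ARPE and -0.268 in BJ, a mean of 0.177 against -0.338. The 6 splits of the 4 lines allow no exact permutation p below 0.33, which is the value for K27me3 and K4me3 (adjusted 0.5 over 6 pairs of marks). For K9ac the exact p was 0.67 (adjusted 0.8). With normexp values the hESC mean with K27me3 was -0.12 (-0.295 in HSF1 and 0.054 in HSF6). That with K4me3 was 0.092 (-0.078 in HSF1 and 0.261 in HSF6). Subtracting the line's H3 array from both marks gave 0.349 in HSF6 and -0.228 in ARPE for K27me3. The subtracted array is shared by both marks, which can raise r by itself.

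**Figure D3:**
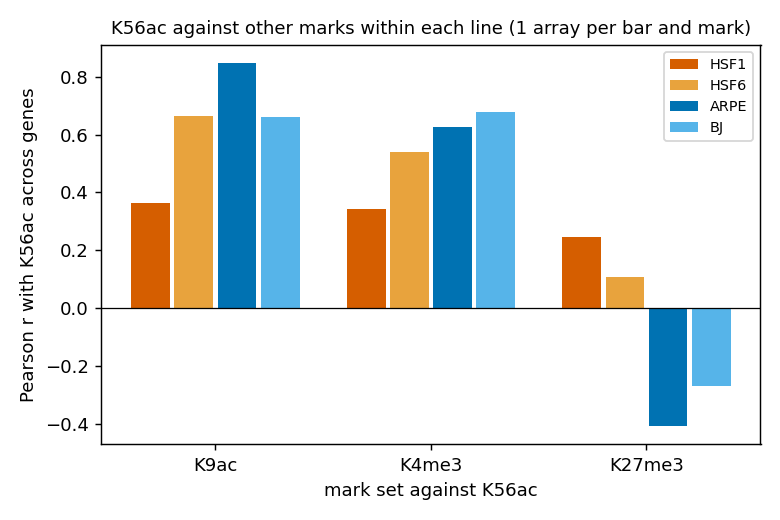
Pearson r across genes (y axis) between K56ac and each of K9ac, K4me3 and K27me3 (x axis) within HSF1, HSF6, ARPE and BJ, 1 array per line and mark. With K27me3 the hESC bars lie at 0.245 and 0.109 and the somatic bars at -0.407 and -0.268. With normexp values the hESC mean was -0.12 (-0.295 in HSF1 and 0.054 in HSF6).

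Promoters that stood out on both arrays of a class were counted without a test. K56ac was enriched at 700 genes in hESC and 165 in somatic lines, 37 of them shared. In hESC these held 30 of 46 pluripotency genes, 37 of 41 histone genes and 14 of 36 stem cell regulators, against 0, 2 and 0 in somatic lines. The cutoff followed each array's own spread, which was narrower in hESC (MAD 0.222 in HSF1, 0.276 in HSF6, 0.697 in ARPE and 0.645 in BJ). A lower log2 ratio therefore sufficed in hESC, and the class counts do not compare equal ratios. The stem cell list, for example, had a median log2 difference of -0.16 between hESC and somatic lines. Of 84 mesenchymal genes 12 were enriched in somatic lines and 6 in hESC. K9ac was enriched at 1126 and 494 genes, and 279 genes carried both acetylations in hESC where independence gives 47.4, and 30 in somatic lines where it gives 4.9. K27me3 was enriched at 1688 and 2139 genes, including 157 of 163 developmental transcription factors in hESC and 110 in somatic lines. Of the K56ac genes 47 in hESC (71.1 if independent) and none in somatic lines (21.2) carried K27me3. By the same rule 9 and 224 genes passed for K4me3 and none for K4me3 and K27me3 together, where the regions that the authors' program called bound gave 690 genes with both in hESC and 312 in somatic lines. The order of the classes turned with normexp values, 19 K56ac genes in hESC and 563 in somatic lines, and the authors' bound regions gave 4779 and 3801. For K9ac the bound regions turned the order, 5318 genes in hESC and 5494 in somatic lines.

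Retinoic acid drives hESC out of the pluripotent state, and 1 array of treated HSF6 was set against 1 of untreated HSF6, with no test. These arrays were scanned in different batches, so treatment and scan batch cannot be told apart. K56ac was lower after treatment at NANOG (-6.63 MAD units), SOX2 (-6.40), DPPA4 (-6.07), PHC1 (-7.14) and the miR-302 cluster (-7.76). It was higher at HOX genes of the retinoic acid response, HOXB1, HOXB5 (3.68), HOXA3 (3.44) and MIR10A, which lies in the HOXB cluster (3.94), and at NNMT (4.39). On the log2 scale NANOG went from 2.14 to 0.43 and HOXB1 from -0.13 to 1.56. The MAD was 0.467 on the treated and 0.276 on the untreated array. A high log2 ratio that stayed the same therefore falls in MAD units, at single genes and in list medians. The histone gene H4C11 differed by -4.29 MAD units while its log2 ratio went from 2.343 to 1.865. GALNT8 (-7.23), FBXO40 (-6.39), LARP7 (-6.01), USP44 (-5.99) and the histone gene H3C11 (-6.25) were also among the 10 lowest. SYCP2 (4.03), TTLL6, SCGB1A1 (3.37), SKA2 (3.32) and ST6GALNAC1 (3.16) were also among the 10 highest. Of the 10 highest 9, all but HOXA3, lie on slide 2, as do 4 of the 10 lowest. Slide 2 of the treated array is doubtful, since its input correlated at a median r of 0.63 with the same slide of the other arrays, against 0.88 to 0.955 for every other slide, and the authors excluded 11646 of its probes. The gains at HOXB1, HOXB5, MIR10A and NNMT rest on this slide, as do the losses at NANOG, PHC1, GALNT8 and USP44.

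The pluripotency list had a median of -2.33 after retinoic acid, below all 10000 matched random lists, whose central range ran from -1.12 to -0.37, and 43 of its 46 members lay below 0. Among random lists matched on the untreated HSF6 value alone, with a central range from -2.04 to -1.28, it stood at percentile 0.07. Stem cell regulators (-1.14, percentile 0.47), led by GJA1 (-5.03) and JARID2 (-3.74), were low as well. Retinoic acid genes (0.72, above all random lists, and 0.69 on slide 1 alone) and mesenchymal genes (0.19, percentile 99.99), with COL3A1 (3.11), were high. Histone genes had a median of -2.85, below all random lists, but stood above all random lists with normexp values. The other 9 lists lay inside their random ranges, the trophoblast list at percentile 97.2 and the neural list at 3.03. With normexp values stem cell regulators moved to percentile 35.64 and mesenchymal genes to 56.4. Across genes the change correlated weakly with the difference between HSF1 and the somatic lines, at r = -0.304 (Spearman -0.169, and r = -0.185 on unscaled and -0.486 on normexp values). These arrays enter neither side of the treatment comparison, but K56ac in HSF1 and untreated HSF6 correlated at r = 0.873. Lost contrast on the treated array would therefore also give a negative r, so no shift toward the somatic lines is read from it. The treated array was the dimmest, and 11927 of its probes were excluded by the authors.

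**Figure D4:**
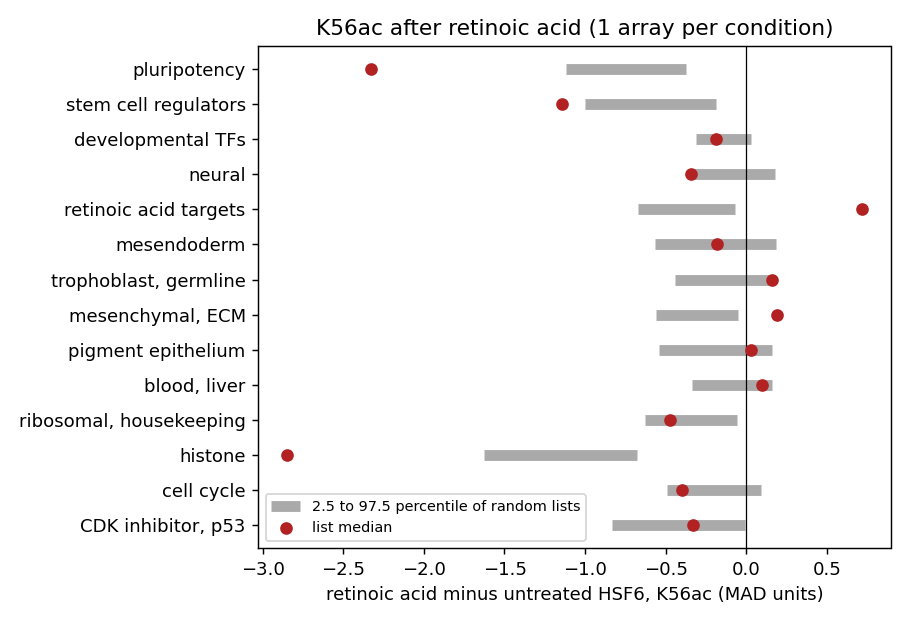
Median K56ac difference of treated minus untreated HSF6 (MAD units, x axis) for 14 gene lists (y axis), 1 array per condition, with grey bars for the central range of 10000 matched random lists. Pluripotency genes lie at -2.33 and retinoic acid genes at 0.72, and the histone median of -2.85 stood on the other side of its random lists with normexp values. For pluripotency genes, random lists matched on the untreated value alone ran from -2.04 to -1.28.

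K56ac relative to H3 was described in HSF6 and ARPE, again with 1 array each. The H3 arrays were scanned in other batches than the K56ac arrays of these lines. In HSF6 high values lay at the miR-302 cluster (16.06 MAD units), at the histone genes H3C2 (15.90), H3C8 (13.16) and H4C5 (12.58), at LIN28B (13.87) and at the gap junction gene GJA1 (12.95). The small nucleolar RNAs U17b (16.65) and SNORD84 (15.44) were as high, and so was UGT2B17 (14.71) with its low H3 value. The lowest lay at zinc finger and olfactory or vomeronasal receptor genes, such as ZNF300 (-6.76) and VN1R2 (-6.71). In ARPE the kinase ABL2 (8.52), OTX2 (8.46), a factor of the eye and forebrain, and MIR21 (7.30) were among the highest and KLRK1 (-9.65) and OR4K15 (-8.73) the lowest.

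By list, histone genes had a median of 8.10 over H3 in HSF6 (percentile 100), pluripotency genes 4.35 and stem cell regulators 3.58. In ARPE histone genes stood at -0.70 (percentile 3.21, and 93.77 with normexp), pluripotency genes at -0.94 (0.35) and mesenchymal genes at 1.70 (100). Mesenchymal genes in HSF6 had 1.02 (100), which moved to percentile 95.65 without scaling, and pluripotency genes in ARPE moved to 21.65. Ribosomal genes (1.92 and 1.44) and CDK inhibitor genes (1.67 and 1.60) were high in both lines, though without scaling the HSF6 percentiles were 95.61 and 86.1. Blood and liver genes were low in both (-1.37 and -1.92), but without scaling the ARPE percentile was 46.79. Developmental transcription factors were high in HSF6 (1.25) and low in ARPE (-0.60), but without scaling the ARPE percentile turned from 0.00 to 93.71. H3 itself ran against K56ac across genes, at r = -0.635 in HSF6 and -0.439 in ARPE.

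Along the promoter K56ac peaked 500 to 1000 bp downstream of the start in HSF1 (0.27), HSF6 (0.38) and BJ (0.64) and 1000 to 1500 bp downstream in ARPE (0.48). H3 was lowest in the 500 bp upstream of the start, -0.13 in both HSF6 and ARPE. K4me3 peaked between 500 and 1000 bp downstream in all 4 lines. K27me3 peaked upstream, between -1500 and -1000 bp in the somatic lines and -1000 and -500 bp in hESC.

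**Figure D5:**
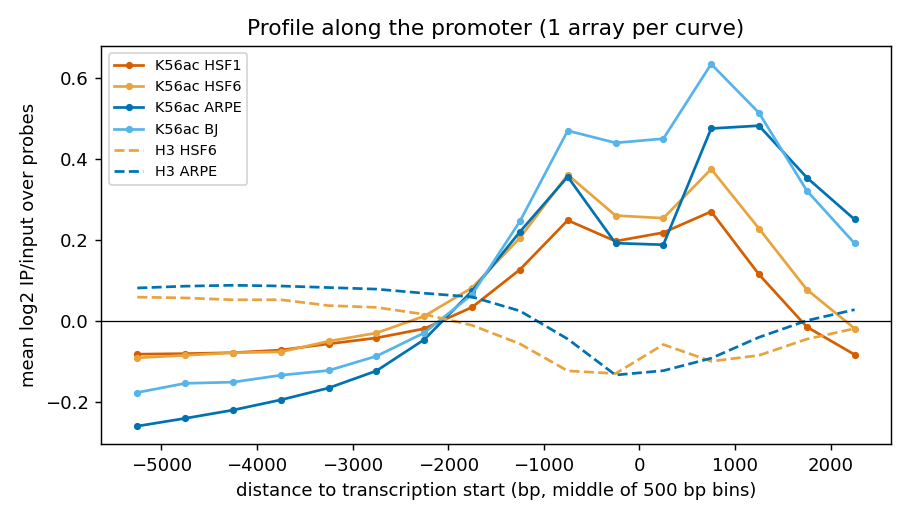
Mean log2 ratio of immunoprecipitate over input (y axis) of K56ac in 4 lines (solid) and H3 in HSF6 and ARPE (dashed) by distance to the transcription start in 500 bp bins (x axis), 1 array per curve. K56ac peaks downstream of the start, at 0.27 in HSF1 and 0.64 in BJ, and H3 is lowest just upstream, at -0.13.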

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

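Of the tests weighed here, those of scan batch and hybridisation strength, of single arrays behind the histone genes, of cross-hybridisation at histone genes without probes upstream, of the retinoic acid slides, and of the authors' normalization for histone genes and for retinoic acid were chosen after the result was seen.

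The signed hESC effect (hESC minus somatic) differed between marks in a test of the difference itself, on values scaled to MAD units within each line (limma, n = 2 lines per class). A lower effect of K56ac is thus not always a smaller one. Against K4me3 the hESC effect of K56ac was higher at 1612 genes and lower at 995, and with normexp at 748 and 1662, so that the larger side turned. The highest were hsa-mir-512-1 (9.488), GALNT8 (8.446), MIR498 (8.427), FBXO40 (7.713), hsa-mir-520e (6.689) and MIR371A (6.443), most of them in the microRNA clusters of chromosome 19. The lowest were OR4K2 (-5.86), OR4K5 (-4.674), OR4K1 (-4.266), GLYAT (-4.216), MIR15A (-4.213) and CCDC121 (-4.181). Without HSF1 the counts became 697 and 198.

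Against K9ac, 2 genes had a higher hESC effect for K56ac, GALNT8 (7.961) and hsa-mir-512-1 (7.412), and 0 a lower one (limma, 1548 and 1342 at an unadjusted p under 0.05). Without HSF6 573 and 999 passed, and without ARPE (556 and 857 at an unadjusted p under 0.05) or BJ (680 and 304) 0 on both sides. On unscaled values limma passed 0 on both sides (2710 and 1813 at an unadjusted p under 0.05).

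K56ac values of the hESC lines covered a narrower range than those of the somatic lines. The SD over genes was 0.283 in HSF1 and 0.344 in HSF6 against 0.705 in ARPE and 0.651 in BJ, a class ratio of 0.46 that was 0.69 for K9ac, 1.24 for K4me3 and 1.04 for K27me3. Scan batch as the whole cause would have brought the ratio within a batch to 0.8 or more, but it was 0.401 for HSF1 over ARPE and 0.529 for HSF6 over BJ. Weak hybridisation of the hESC arrays would have lowered their signal over background, which was 1.1 times that of the somatic arrays. The authors' intensity-dependent normalization stays open, because with normexp values, which leave it out, the ratio was 0.54 in one batch and 0.838 in the other. So do an antibody that reacts differently by chromatin and a difference between the classes in K56ac itself, neither of which was tested.

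K56ac at replication-dependent histone genes was higher in hESC, with a list median of 0.41. A single array or scan batch as the cause would have brought the median below 0.1 in a batch, and the lower of the batch medians was 0.29. Cross-hybridisation between near-identical coding sequences as the whole cause predicts no difference outside them, but probes more than 500 bp upstream had a median of 0.619 (bootstrap SE 0.184, above 0 at all 20 genes that have such probes). At the other genes, probes more than 1000 bp downstream, past the short coding sequence, had a median of 0.433 (bootstrap SE 0.161, above 0 at 16 of 20 genes), which argues against it there too. The authors' normalization is a candidate explanation, since with normexp the median was -0.11 (camera adjusted p = 0.216, range 3.16e-17 to 0.651 over the alternatives). Normexp also replaces the authors' background correction, so the change cannot be assigned to a single step. With loess on the normexp values the median was 0.19 (camera adjusted p = 4.82e-04). A class difference in histone gene chromatin remains untested.

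K56ac at pluripotency genes was lower after retinoic acid, with a list median of -2.33 MAD units. Loss of contrast on the dim treated array would lower every gene with a high untreated value alike. Random lists matched in 100 bins on the untreated value fell too, to a median of -1.65 (central range -2.04 to -1.28). Much of the fall was thus shared by genes with like untreated values, and the pluripotency list differed from that median by a further -0.682 (percentile 0.07). Within the highest bin untreated values can still differ, so the match is not exact. Slide 2 of the treated array is not the whole cause, since slide 1 alone gave -2.68. Nor is the authors' normalization, since with normexp the median was -0.31 where random lists ran from 0.38 to 1.59. An effect of retinoic acid on these promoters may explain the pattern, as a hypothesis from 1 treated array that was found and tested on the same data. A difference between single cultures or between the scan batches of the treated and untreated arrays was not tested and stays open.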

How the results depend on the processing

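Centring each slide on its own median, single slides of the retinoic acid array and the authors' bound regions were added after seeing the data. The cause of the changes named below was not tested. Where a line was left out, the class with 1 line has no spread of its own, and its lone sample is assumed to vary like the others. Camera takes no block, so list tests with the cell line as a block were not run. Signal over background limits how well low ratios are resolved.

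Of 196 alternative gene counts 127 stayed within 1.5 times the reported count. These include K9ac counts of 0 against a reported 0, which do not inform on stability. A like count also need not hold the same genes. With MAD scaling 1292 genes were higher for K56ac, and 732 of them were among the 1899 reported. Of 1428 alternative list results 1259 counted as the same, 131 lost the call, 28 gained one and 10 turned direction. A turn was counted only where either result passed, and otherwise as the same. K56ac stem cell regulators, for example, turned to lower with normexp (camera adjusted p = 0.418) without being counted. By the same rule 4092 of 4954 results for named genes were the same, 779 lost and 73 gained the call and 10 turned. The same ones include K9ac genes, none of which had passed to begin with. For genes that differ between marks 62 of 84 were the same, 20 lost the call and 2 turned. For correlations 13 of 24 stayed within the spread between lines, for counts of differences between marks 12 of 24, and for enriched promoters 11 of 40. For retinoic acid lists 25 of 30 and for K56ac over H3 32 of 46 stayed on the same side of their random lists.

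With normexp background correction 521 genes were higher for K56ac, 9 higher and 22 lower for K4me3 and 422 and 494 for K27me3. The histone list median for K56ac became -0.11 (adjusted p = 0.216, range 3.16e-17 to 0.651). K56ac correlated with K9ac at a mean of 0.52 in somatic lines and with K4me3 at 0.092 in hESC and 0.575 in somatic lines. With K27me3 the hESC mean was -0.12, so that its sign turned. Only HSF1 turned (-0.295), while HSF6 stood at 0.054. K56ac exceeded K4me3 in signed hESC effect (hESC minus somatic) at 748 genes and fell short at 1662, and fell short of K9ac at 46. Here and below, exceeding and falling short refer to this signed effect and not to its size. Enriched promoters in hESC and somatic lines were 19 and 563 for K56ac, 282 and 114 for K9ac, 186 and 675 for K4me3 and 686 and 746 for K27me3. The histone list after retinoic acid moved to percentile 100. The K56ac difference turned at GAP43 (-0.024, adjusted p = 0.954, range 8.88e-04 to 0.954), IKZF1 (-0.006, 0.989, range 6.9e-04 to 0.989) and H2BC15 (-0.13, 0.737, range 8.1e-03 to 0.773). The difference from K4me3 turned at OR4K1 (0.255) and MIR15A (0.528).

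With MAD scaling 1000 genes were lower for K56ac, 5 higher for K9ac, 70 higher and 193 lower for K4me3 and 224 and 360 for K27me3. List directions turned, with medians in MAD units, for ribosomal genes in K56ac (0.29, adjusted p = 0.274, range 2.03e-06 to 0.62), K9ac (0.28, 9.98e-04, range 1.85e-07 to 0.773) and K4me3 (-0.18, 0.0953, range 4.38e-04 to 0.963). In K9ac they also turned for blood and liver (0.0196, 0.868, range 3.59e-09 to 0.868), developmental (-0.12, 0.0388, range 1.85e-05 to 0.904) and trophoblast genes (0.0213, 0.813, range 1.17e-04 to 0.813). Centring on the mode gave 1042 genes lower for K56ac and 135 higher and 4685 lower for K4me3. Loess gave 0 higher and 1 lower for K56ac (limma, 698 and 1770 at an unadjusted p under 0.05), 88 and 302 for K4me3 and 296 and 434 for K27me3.

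With the 3 adjacent probes of highest mean, 377 genes were higher for K56ac, 247 higher and 158 lower for K4me3 and 608 lower for K27me3. Cell cycle genes, which did not pass for K56ac (camera direction lower), passed as higher (adjusted p = 0.0481, range 0.0307 to 0.988) although their median was -0.22. K56ac correlated with K4me3 at 0.607 in hESC and 0.708 in somatic lines and with K27me3 at -0.196 in somatic lines. Enriched promoters were 30 for K56ac in somatic lines, 1890 and 1092 for K9ac and 0 and 0 for K4me3. Directions turned at SOX2 (-0.86, adjusted p = 0.449, range 1.38e-03 to 0.449), TBXT (-0.29, 0.505, range 1.46e-03 to 0.505) and IKZF1 (-0.061, 0.887, range 6.9e-04 to 0.989) for K56ac, ZP2 for K4me3 (0.11, 0.935, range 5.7e-05 to 1.0) and SOX2 (1.30, 0.0327, range 4.21e-03 to 0.585) and LIN28B (0.25, 0.565, range 2.14e-04 to 0.565) for K27me3.

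Probes within 1000 bp of the start gave 603 genes higher and 840 lower for K56ac and 396 and 501 for K27me3. Cell cycle genes passed as higher for K56ac (median 0.0521, adjusted p = 0.0307, range 0.0307 to 0.988), and SKIL turned for K4me3 (-0.048, adjusted p = 0.976, range 4.86e-04 to 1.0). The median over probes gave 559 genes lower for K4me3 and 356 higher for K27me3. The trend and robust options gave 171 and 201 for K9ac and 1299 and 1612 for K4me3. An adjusted p under 0.1 gave 2950 genes higher for K56ac, 940 and 1501 for K4me3 and 1151 higher for K27me3. Under 0.01 limma gave 0 and 0 for K56ac (3011 and 4902 at an unadjusted p under 0.05), 74 and 192 for K4me3 and 101 and 120 for K27me3. The fit over 16 arrays gave 759 and 1357 for K4me3 and 1037 higher for K27me3, and with the cell line as a block 809 and 1362, and 1031.

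With an estimated correlation the K56ac lists had adjusted p = 0.62 for developmental transcription factors (median 0.28), mesenchymal (-0.89) and pluripotency genes (1.06) and 0.651 for histone genes (0.41). With fry these were 0.323, 0.111, 0.111 and 0.5. Their ranges over the alternatives were 2.3e-15 to 0.62, 1.52e-16 to 0.62, 1.85e-24 to 0.62 and 3.16e-17 to 0.651. No list of any mark passed with an estimated correlation, so this alternative does not tell whether correlation between genes undid a call.

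The Spearman correlation of K56ac and K27me3 in hESC was 0.316. Unscaled values gave 0 genes with a higher effect of K56ac than of K9ac (limma, 2710 higher and 1813 lower at an unadjusted p under 0.05), and 2962 higher and 2130 lower than of K4me3. For K56ac over H3 they gave percentiles of 95.65 for mesenchymal genes in HSF6, and in ARPE 21.65 for pluripotency, 93.71 for developmental, 99.07 for neural, 58 for mesoderm and endoderm and 67.35 for trophoblast genes. A threshold of 3 times the lower-side spread gave 223 and 6 enriched promoters in hESC and somatic lines for K56ac, 392 and 73 for K9ac, 0 and 3 for K4me3 and 1046 and 1267 for K27me3. The authors' bound regions gave 4779 and 3801, 5318 and 5494 for K9ac, 5063 and 5134 for K4me3, and 690 and 312 with both K4me3 and K27me3. On slide 2 alone the 1 histone gene there lay at percentile 27.92 after retinoic acid.

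Leaving out each line in turn gave 0 to 3900 genes higher and 0 to 5549 lower for K56ac, 0 to 562 and 0 to 1082 for K4me3 and 0 to 1395 and 0 to 2070 for K27me3. The counts of 0 came without HSF1 and without HSF6 (limma, with 1358 and 2147, and 1364 and 3076 for K56ac at an unadjusted p under 0.05). The K9ac list of developmental transcription factors ran from -0.0465 (adjusted p = 0.0742) to 0.063 (1.52e-04). K56ac exceeded K9ac in hESC effect at 0 to 573 genes and fell short at 0 to 999, with 0 on both sides without ARPE or BJ (limma, 556 and 857, and 680 and 304 at an unadjusted p under 0.05), and exceeded K4me3 at 697 to 1744 and fell short at 198 to 1349.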

Other observations

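The marks other than K56ac were also compared with each other within each line, across genes that are not independent replicates. K9ac and K4me3 correlated at a mean r of 0.711 in hESC and 0.712 in somatic lines (exact permutation p = 1.0, adjusted 1.0 over 6 pairs of marks), and with normexp values at 0.34 and 0.708. K27me3 ran with K4me3 in hESC (0.223) and against it in somatic lines (-0.124), and its r with K9ac was -0.055 and -0.314 (exact permutation p = 0.33 each, adjusted 0.5). With normexp values the K9ac pair with K27me3 gave -0.33 and -0.314. The normexp hESC mean of 0.34 for K9ac and K4me3 joined -0.096 in HSF1 and 0.777 in HSF6.

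The retinoic acid array resembled the hESC lines more than the somatic lines across genes. Its K56ac values correlated at r = 0.69 with HSF1 and 0.66 with untreated HSF6, against 0.5 with ARPE and 0.525 with BJ.

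H3 ran against the marks of active promoters. In HSF6 it correlated at r = -0.499 with K9ac and -0.521 with K4me3, and in ARPE at -0.381 and -0.358. With K27me3 the r was -0.133 in HSF6 and 0.117 in ARPE, and the H3 arrays of the 2 lines correlated at 0.437. The H3 ratios covered a small range, with an SD over genes of 0.143 in HSF6 and 0.125 in ARPE, so MAD units over H3 magnify small log2 differences.

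UGT2B17 had a log2 H3 value of -2.92 in HSF6, far below other genes, and its K56ac value there was also low (-8.15 MAD units). A ratio that is low for the histone itself and for a mark of it sets this gene apart from the other genes of high K56ac over H3, such as LIN28B, at which K56ac was high (7.15 MAD units). No copy number was measured.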
